A study of Homo sapiens with 18 samples.

How the data were processed

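RNA of OCI-AML1 cells was extracted with TRIzol and a column kit, selected for polyadenylated RNA and sequenced in 18 libraries, 3 for each of 6 groups, per the labels. The authors aligned the reads to GRCh38 with STAR 2.7.1a and deposited 1 file of read counts per library, in the layout of STAR gene counts with an unstranded, a forward and a reverse column. The deposited files also include RSEM 1.3.2 gene results, in which the authors give expected counts and TPM, which are scaled for gene length and depth. The TPM values were not used, because tests of counts need unscaled values. The annotation release of the authors is not given. Of 60609 gene identifiers, 60340 had a symbol in a reference list of gene names and 58502 were in GENCODE release 29, which gave the positions.

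The reverse column was used, by a rule that asked for over 80% of the unstranded counts. Reverse counts were 1.045 to 1.049 times the unstranded counts and forward counts 6.27 to 6.66% of the reverse counts. The 4 summary lines of each file were left out and held 21.94 to 25.52% of the reads. Unmapped reads were 5.42 to 9.22%, reads with several alignments 6.36 to 6.75%, reads in no gene 5.75 to 7.4% and ambiguous reads 3.71 to 3.99%. Counts in genes ranged from 98975944 to 142496541 per library. A gene with 0 counts had an upper 95% limit of 3 counts, or 0.0211 to 0.0303 CPM. This limit covers counting error and not the spread between cultures. Reads with several alignments are not counted, which affects multigene families such as the HLA genes, and mitochondrial genes have nuclear copies.

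Genes were filtered with filterByExpr, which left 20920 genes, 13339 of them protein coding, and removed 0.016% of the counts. Counts were scaled with TMM, and 1 model with the 6 groups was fitted by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with 12 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Each compound was compared with DMSO at each time, the compounds with each other at each time, DMSO at 24 h with DMSO at 8 h, and the effect of each compound at 24 h with its effect at 8 h. Gene lists, 38 in number, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, with at least 3 tested members. Camera with an estimated correlation and the rotation test fry were alternatives. The tests, lists and alternatives were chosen before the data were examined, with some exceptions. These were the HIF target list, the B cell list, the settings built on the HIF targets and the tests stated as later choices. Leaving out the 4 libraries highest on the main axis of variation within groups was also a later choice.

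The named genes were protein coding with a mean of at least 5 CPM in the higher group and with every library of one group above every library of the other. The 10 largest rises and 10 largest falls were named for each comparison with DMSO, and 5 each way for the other comparisons, where differences of effects needed no separation of libraries. Up to 4 members of a list were named by p, and 14 genes of the BCL2 family, the Mediator kinase module and MYC in every comparison. Some genes that this rule names are not reported here.

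Alternatives were median-of-ratios size factors, library totals alone, DESeq2 1.42.0, limma-voom, filters of 1 count and of 1 CPM in 3 libraries, a block for the replicate number, a model of only the groups compared, unstranded counts, rounded RSEM expected counts and leaving out each library in turn. The variation within groups was described by principal components of 9762 genes after the group means were removed. Splits of the libraries into other groups were tested with the same model, and ratios of rises to falls have exact binomial intervals, which treat genes as independent. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The model was tested on simulated data with planted changes, where 20549 genes passed the filter. Changes of single genes were planted only in genes of at least 1 CPM with DMSO at 24 h, so recovery in weaker genes was not measured. The model recovered 84.0% of changes of 1.25-fold, 100.0% of 1.5-fold and 98.0% of 2-fold. It made 23 false calls among the 20328 unchanged genes that were tested. The true calls beside them were 42, 50, 49 and 50 of the 50 genes planted at each of 1.25-fold, 1.5-fold, 2-fold and 4-fold. Planted glycolysis genes could add at most 21 true calls. In this simulation the share of false calls among all calls was therefore above the adjusted p threshold. A planted change of the glycolysis list was found (camera adjusted p = 1.79e-55) with 0 of 37 other lists called. Each gene was drawn independently, so the simulation cannot show how often camera calls unchanged lists whose members vary together.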

Results

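Polyadenylated RNA was sequenced from OCI-AML1, a human acute myeloid leukaemia cell line, after culture with the solvent DMSO, with AML874 or with SEL120-34A for 8 h or 24 h. SEL120-34A is an inhibitor of CDK8 and CDK19, the kinases of the Mediator complex, which links transcription factors to RNA polymerase II. AML874 is a code name, and no dose is given for either compound. Each of the 6 groups held 3 libraries. Gene counts per library ranged from 98975944 to 142496541, and 25852 to 28631 genes had at least 1 count. The title of the series concerns Mediator kinase inhibition and sensitivity to venetoclax, a BCL2 inhibitor, so each compound was compared with DMSO, the compounds were compared with each other, and the times were compared within each treatment. Changes are log2 fold changes with their standard error (SE), and levels are in CPM, counts scaled by library size, with their standard deviation (SD), with n = 3 libraries a group throughout.

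The first comparison asked which transcripts AML874 changed after 8 h. EGR1, an immediate early transcription factor (ENSG00000120738.8, GRCh38 chromosome 5, 138465490 to 138469315), went from 65.9 ± 20.3 CPM with DMSO to 4.71 ± 0.287 CPM, a log2 change of -3.81 ± 0.25 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.14e-08). HEXIM1, which holds the elongation factor P-TEFb inactive, had a log2 change of -1.57 ± 0.04, from 60.5 ± 1.57 to 20.3 ± 0.803 CPM. H1-10, a linker histone gene, had a log2 change of -1.24 ± 0.03, and BMF, a pro-apoptotic member of the BCL2 family, had -1.29 ± 0.08. TAF9B, RBM14, RGL4, EMILIN1 and RAB15 also fell, with log2 changes between -1.62 and -1.18. MPEG1, a pore-forming protein of macrophages, rose by 1.38 ± 0.04 on the log2 scale, from 35.2 ± 1.34 to 91.6 ± 2.94 CPM. MS4A4A and MS4A6A, neighbouring membrane protein genes on chromosome 11, rose by 1.60 ± 0.04 and 1.36 ± 0.03. DNHD1, GREB1, SYTL2, ZP3, MEGF10, NMNAT1 and ACTA2 were the other named rises, between 1.16 and 1.46.

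Among the gene lists at 8 h with AML874, 18 of 29 immediate early and AP-1 genes fell and 0 rose, with a median of -0.40. IER2 (-0.58 ± 0.04), JUNB (-0.42 ± 0.04) and KLF2 (-0.73 ± 0.09) fell with EGR1. DNA replication and G1/S genes fell in 24 of 31, with RRM2, a subunit of ribonucleotide reductase, at -0.60 ± 0.02 and CCNE2, a cyclin, at -0.47 ± 0.04. The camera test gave adjusted p = 3.47e-05 for the first list and 3.43e-07 for the second, and each gave adjusted p = 0.556 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 24, among them MVD by 0.91 ± 0.07 and HSD17B7 by 0.53 ± 0.05, and endoplasmic reticulum chaperones rose in 9 of 16, among them HYOU1 by 0.54 ± 0.03 and CALR by 0.27 ± 0.02. Their adjusted p was 0.000323 and 0.0047, and with an estimated correlation adjusted p = 0.627 and 0.556. Glycolysis genes fell in 12 of 21 and rose in 2, with ALDOA at -0.42 ± 0.06 and GAPDH at -0.22 ± 0.03, while PFKL and PFKM, phosphofructokinase subunits, rose by 0.21 ± 0.03 and 0.24 ± 0.04. Its adjusted p was 0.0065, and adjusted p = 0.639 with an estimated correlation.

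The rest of the 10 called lists were haematopoietic transcription factors, where 15 of 32 fell and 5 rose, NRF2 targets, where 9 of 14 fell, lysosome and autophagy genes, where 13 of 25 fell, mitochondrial protein synthesis and import, where 10 of 26 rose, and MHC class II presentation, where 6 of 10 rose. In the first of these NFE2 had a log2 change of -1.03 ± 0.08, while IRF8 and MEF2C rose by 0.40 ± 0.02 and 0.43 ± 0.03. These 5 lists had adjusted p from 0.556 to 0.639 with an estimated correlation. Adjusted over the list alone, the counts changed to 16 falls and 6 rises for the haematopoietic transcription factors and to 15 falls for the lysosome list, and stayed as given for the other lists. Genes of the hypoxia response separated libraries of the same group and varied with the glycolysis genes. The mean of 22 HIF targets was 4.61 to 5.27 log2 CPM in the DMSO libraries and 4.49 to 4.54 in the AML874 libraries at 8 h, and EGR1 was among the genes at the high end of that variation.

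Of 20920 genes tested, 8287 changed with AML874 at 8 h, 4125 higher and 4162 lower, and 9681 had an unadjusted p under 0.05. By at least 2-fold, 745 genes rose and 144 fell, most of them weakly expressed: with a filter of 1 CPM in 3 libraries 168 rose and 32 fell. The share of changed genes that were higher was 49.8%, and it was 63.5% with library totals alone in place of TMM scaling. The p-values measure the spread between these libraries, and nothing in the labels says whether replicates were separate cultures.

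For SEL120-34A the same question was asked at 8 h. EGR1 had a log2 change of -3.06 ± 0.23 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.62e-07), to 7.91 ± 1.23 CPM. RBM14, an RNA-binding protein gene, had -1.66 ± 0.04, and BCLAF1, a gene for a BCL2-associated transcription factor, had -1.05 ± 0.03, from 308.6 ± 2.39 to 149.0 ± 2.38 CPM. TAF9B had -1.41 ± 0.06. RGL4, OLIG1, EMILIN1, NANOS1 and PPP1R27 also fell, with log2 changes between -1.47 and -1.01. SCART1, a scavenger receptor family gene, rose by 2.42 ± 0.12, from 0.957 ± 0.176 to 5.08 ± 0.353 CPM. MS4A4A rose by 1.67 ± 0.04 and DNHD1 by 1.68 ± 0.07. NR1H3, which encodes a liver X receptor, rose by 1.43 ± 0.07, and C3AR1, the receptor of the complement fragment C3a, by 1.58 ± 0.28. TOX, ENPP2, SYTL2 and ATP6V1FNB rose by 1.32 to 1.40, and RXFP1 was the last of the 10 named rises.

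With SEL120-34A at 8 h, DNA replication and G1/S genes fell in 26 of 31, with POLA1, a DNA polymerase subunit, at -0.63 ± 0.03, CCNE2 at -0.66 ± 0.04 and RRM2 at -0.56 ± 0.02. The list had adjusted p = 1.05e-10 with camera, and adjusted p = 0.818 with an estimated correlation. p53 targets rose in 14 of 26 and fell in 3, among the rises EDA2R by 0.73 ± 0.05, TIGAR by 0.61 ± 0.05 and XPC by 0.46 ± 0.03. Primary granule genes fell in 8 of 11, with MPO, the myeloperoxidase gene, at -0.85 ± 0.06 and RNASE2 at -0.34 ± 0.03. These lists had adjusted p = 0.00605 and 0.00612, and with an estimated correlation adjusted p = 0.941 and 0.28. MYC and nucleolar targets fell in 15 of 26 and rose in 3, with DKC1 at -0.26 ± 0.03, NRF2 targets fell in 9 of 14, with TXNRD1 at -0.26 ± 0.03, and glycolysis genes fell in 12 of 21, with ALDOA at -0.47 ± 0.06 and PFKL higher by 0.15 ± 0.03. Each of these 3 had adjusted p = 0.941 with an estimated correlation. The mean of the HIF targets in these libraries was 4.40 to 5.03 log2 CPM. Adjusted over the list alone, 28 replication genes, 16 MYC and nucleolar targets and 10 NRF2 targets fell, and 5 p53 targets fell, with the other counts as given.

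SEL120-34A changed 9425 genes at 8 h, 4693 higher and 4732 lower, and 10634 had an unadjusted p under 0.05. By at least 2-fold, 1084 rose and 209 fell, or 240 and 37 with the filter of 1 CPM. The share higher was 49.8%, and 66.5% with library totals alone.

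**Figure D1:**
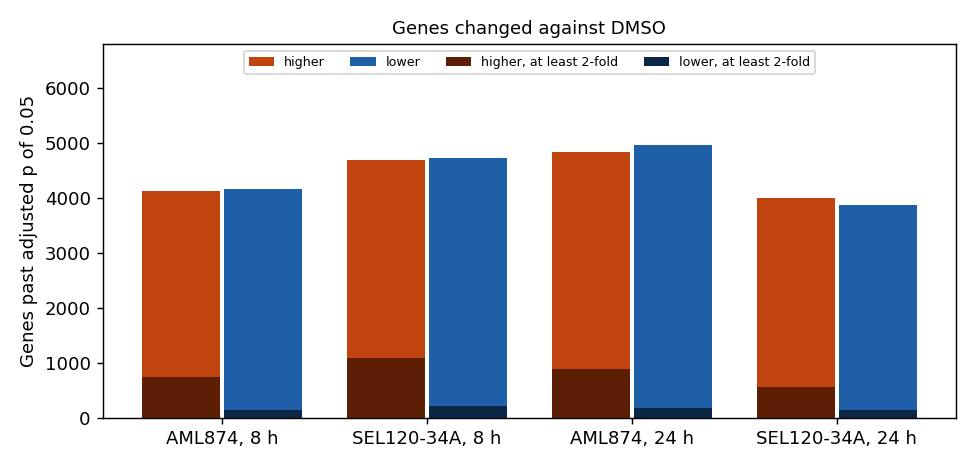
Number of genes past an adjusted p of 0.05 against DMSO in each of the 4 comparisons, split into higher and lower, with the part changed at least 2-fold drawn darker. With TMM scaling, changed genes were split about evenly by direction, while 2-fold rises outnumbered 2-fold falls, as in the 745 and 144 genes of AML874 at 8 h. The even split at 8 h depended on the scaling. With library totals alone the share higher was 63.5% with AML874 and 66.5% with SEL120-34A at 8 h, and 49.2% and 48.2% at 24 h.

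At 24 h, CD34, a surface protein of haematopoietic progenitors (ENSG00000174059.17, chromosome 1, 207880972 to 207911402), rose with AML874 by 3.12 ± 0.11, from 0.716 ± 0.0855 to 6.22 ± 0.723 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.91e-22). MPO (ENSG00000005381.8, chromosome 17, 58269856 to 58280935) had a log2 change of -2.87 ± 0.07, from 35.0 ± 2.24 to 4.79 ± 0.473 CPM (adjusted p = 5.23e-26). EGR1 also had -2.87 ± 0.22, from 114.7 ± 14.0 to 15.7 ± 2.65 CPM. MPEG1 rose by 2.44 ± 0.04, to 206.6 ± 6.87 CPM, MS4A4A by 1.95 ± 0.04 and the receptor gene GPR174 by 2.62 ± 0.07. GBP4 and RSAD2, which interferons induce, rose by 2.16 ± 0.08 and 2.15 ± 0.08, and HLA-DOA, which modulates peptide loading of MHC class II, by 2.13 ± 0.11. SDK2, GGT5 and FMN1 rose by 1.78 to 1.97. The myeloid lectin gene CLEC5A had -2.01 ± 0.13, the chemokine gene CCL2 -1.65 ± 0.16, and SSH3, KCNE3, TNFRSF12A, MMP25 and TSPOAP1 lay between -1.80 and -1.43.

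MHC class II presentation genes rose in 10 of 10 with AML874 at 24 h, with a median of 0.84. CIITA, their transcriptional activator and named outside the rule, rose by 0.88 ± 0.04, HLA-DMA by 1.07 ± 0.05 and HLA-DRA by 0.70 ± 0.03, from 242.5 ± 9.51 to 393.4 ± 3.92 CPM. The camera adjusted p was 6.65e-09, and adjusted p = 0.0138 with an estimated correlation, the only 1 of the 19 lists called in this comparison that held with it. MHC class I presentation genes rose in 11 of 15, among them TAP1 by 0.71 ± 0.03 and PSMB9 by 0.66 ± 0.04, and interferon-stimulated genes rose in 21 of 40 and fell in 6, with a median of 0.34 and IFIT3 at 0.87 ± 0.07. Their calls did not hold with an estimated correlation (adjusted p = 0.142 and 0.441). Mitochondrially encoded genes rose in 12 of 13, with MT-CO1 at 0.44 ± 0.03 (adjusted p = 0.239 with an estimated correlation). Mitochondrial genes took 7.74 to 8.16% of the counts in these libraries and 6.11 to 6.18% in the DMSO libraries at 24 h. Ribosomal protein genes rose in 25 of 33, with RPL15 at 0.21 ± 0.02, and nuclear-encoded oxidative phosphorylation genes in 15 of 36, with NDUFV1 at 0.27 ± 0.02. These lists had adjusted p = 0.504 and 0.616 with an estimated correlation.

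Among the lists that fell with AML874 at 24 h, immediate early and AP-1 genes fell in 17 of 29, with a median of -0.54 and ETV5 at -1.37 ± 0.06. STAT5 and cytokine feedback targets fell in 10 of 15, with PIM1 at -0.52 ± 0.03 and CCND3 at -0.67 ± 0.04, and TGF-beta and SMAD targets in 9 of 14, with SMAD6 at -0.64 ± 0.04. In that order these lists had adjusted p = 0.339, 0.142 and 0.142 with an estimated correlation. Genes of mitosis fell in 18 of 26, with MKI67 at -0.48 ± 0.03 and CDK1 at -0.40 ± 0.03, and DNA replication genes in 23 of 31, with RRM2 at -0.54 ± 0.02. Both calls ended with an estimated correlation (adjusted p = 0.373 and 0.428). Primary granule genes fell in 6 of 11, with AZU1 at -1.48 ± 0.14 beside MPO, while CTSG, the cathepsin G gene, rose by 0.42 ± 0.07 (adjusted p = 0.183 with an estimated correlation). Transcription elongation factors and kinases fell in 13 of 21, with HEXIM1 at -1.23 ± 0.04 and BRD2 at -0.28 ± 0.02, while AFF1 rose by 0.53 ± 0.07 (adjusted p = 0.142 with an estimated correlation). Glycolysis genes fell in 15 of 21, with ALDOA at -0.83 ± 0.06 and HK1 at -0.32 ± 0.03 (adjusted p = 0.483 with an estimated correlation). The mean of the HIF targets was 4.97 to 5.32 log2 CPM in these libraries and 5.35 to 5.60 with DMSO at 24 h.

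The other lists that fell with AML874 at 24 h were heat shock genes (10 of 14, HSP90AA1 at -0.61 ± 0.03), NF-kappaB and inflammatory genes (12 of 23, TNFAIP2 at -0.65 ± 0.07), NRF2 targets (9 of 14, ME1 at -1.06 ± 0.07), MYC and nucleolar targets (14 of 26, MYC at -0.23 ± 0.03) and ATF4 targets (13 of 24, TRIB3 at -0.45 ± 0.04). Their adjusted p with an estimated correlation ran from 0.142 to 0.695. The ATF4 list had a median of -0.18 and a mean of 0.05, so its mean had the opposite sign to its median and test. Adjusted over the list alone, the counts differed by at most 2 genes from those over all genes in each of the 19 lists. With that adjustment 27 ribosomal protein genes rose, while 19 mitosis genes, 24 replication genes, 7 granule genes, 11 STAT5 targets, 11 heat shock genes and 16 glycolysis genes fell. AML874 changed 9799 genes at 24 h, 4833 higher and 4966 lower, and 10854 had an unadjusted p under 0.05. By at least 2-fold, 892 rose and 187 fell, or 242 and 70 with the filter of 1 CPM.

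**Figure D2:**
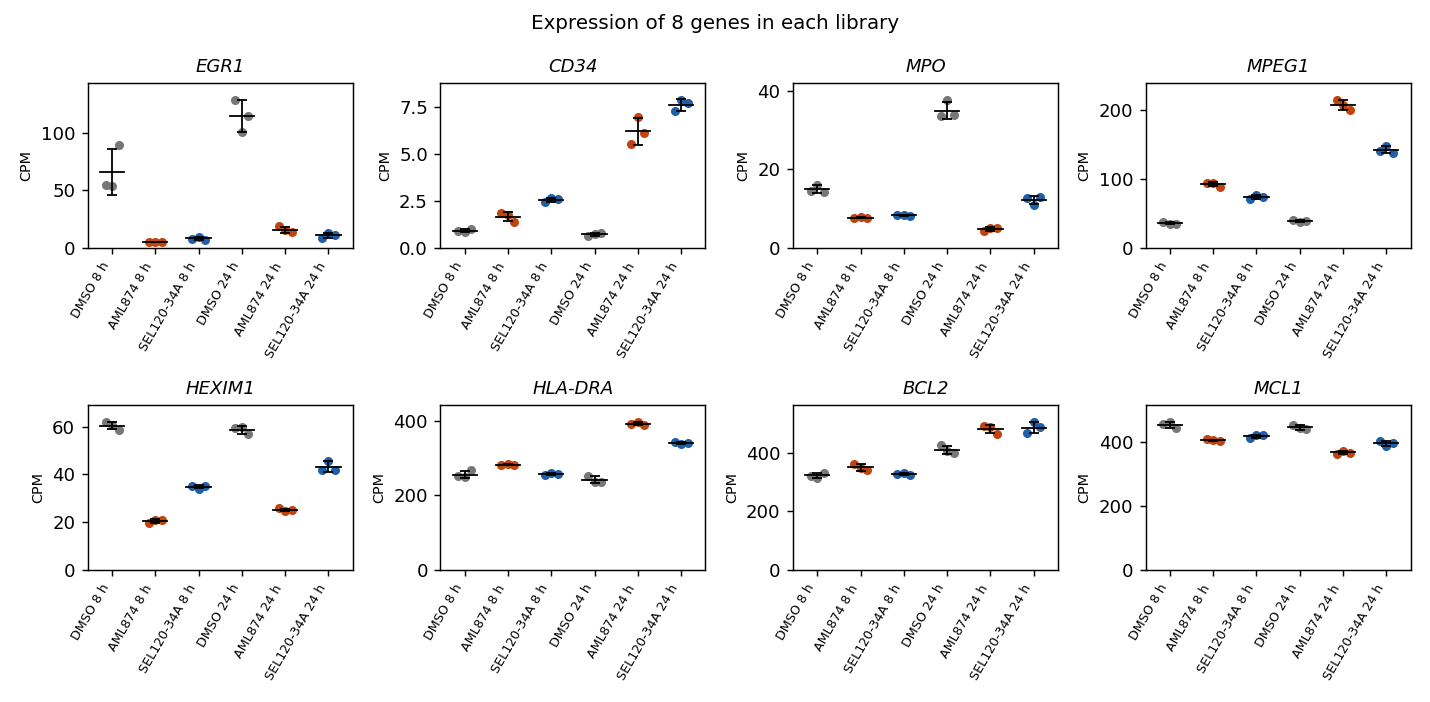
CPM of 8 genes in each of the 18 libraries, with points for libraries and a line and bars for the mean and SD of the 3 libraries of a group. All axes start at 0; CD34, MPEG1 and HLA-DRA were higher with both compounds at 24 h, EGR1, MPO, HEXIM1 and MCL1 were lower, and BCL2 was 411 CPM with DMSO, 481.6 CPM with AML874 and 486.6 CPM with SEL120-34A.

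SEL120-34A at 24 h raised CD34 by 3.41 ± 0.11, to 7.63 ± 0.307 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.8e-23). GPR174 rose by 2.57 ± 0.07, MPEG1 by 1.89 ± 0.03, MS4A4A by 1.79 ± 0.04 and GBP4 by 1.70 ± 0.08. RAB7B, which encodes a small GTPase of late endosomes, rose by 2.41 ± 0.12, SERPINB2, an inhibitor of plasminogen activators, by 1.85 ± 0.14, and GGT5, MYOM1 and SDK2 by 1.69 to 2.07. EGR1 had a log2 change of -3.45 ± 0.23, to 10.6 ± 2.35 CPM, and NAB2, a corepressor of EGR proteins, had -1.18 ± 0.09. MPO had -1.53 ± 0.06, CCL2 -1.58 ± 0.16 and the integrin gene ITGAX -1.11 ± 0.13. ZFP36L1, TNFRSF12A, KCNE3 and DLG4 lay between -1.26 and -1.12.

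MHC class II presentation genes rose in 9 of 10 with SEL120-34A at 24 h, with a median of 0.54, CIITA at 0.69 ± 0.04 and HLA-DRA at 0.50 ± 0.03. The remaining gene, HLA-DQB1, also named outside the rule, was at 0.56 ± 0.31 and did not pass. The camera adjusted p was 3.22e-08, and adjusted p = 0.019 with an estimated correlation, the only 1 of the 10 called lists that held with it. MHC class I genes rose in 10 of 15 and fell in 1, with TAP1 at 0.53 ± 0.03, ribosomal protein genes rose in 19 of 33, and p53 targets rose in 13 of 26 and fell in 2, with TP53I3 at 0.91 ± 0.04 and PLK3 at -0.58 ± 0.06. With an estimated correlation their adjusted p = 0.305, 0.686 and 0.686. Immediate early and AP-1 genes fell in 17 of 29, with SPRY2 at -0.65 ± 0.04, STAT5 targets in 9 of 15, with ID1 at -0.68 ± 0.06, and NF-kappaB and inflammatory genes in 13 of 23, with ICAM1 at -0.60 ± 0.07. The same lists had adjusted p = 0.463, 0.202 and 0.54 with an estimated correlation. Glycolysis genes fell in 13 of 21, with ALDOA at -0.75 ± 0.06, DNA replication genes in 13 of 31, with CCNE2 at -0.63 ± 0.04, and NRF2 targets in 7 of 14, with ME1 at -0.85 ± 0.07. None of the 3 held with an estimated correlation (adjusted p = 0.686, 0.686 and 0.484). The mean of the HIF targets was 5.03 to 5.48 log2 CPM in these libraries.

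Adjusted over the list alone, 22 ribosomal protein genes and 14 p53 targets rose, and 17 glycolysis genes, 9 NRF2 targets and 3 p53 targets fell with SEL120-34A at 24 h, and 2 glycolysis genes rose. SEL120-34A changed 7879 genes at 24 h, 3996 higher and 3883 lower, and 9389 had an unadjusted p under 0.05. By at least 2-fold, 568 rose and 142 fell, or 131 and 37 with the filter of 1 CPM.

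**Figure D3:**
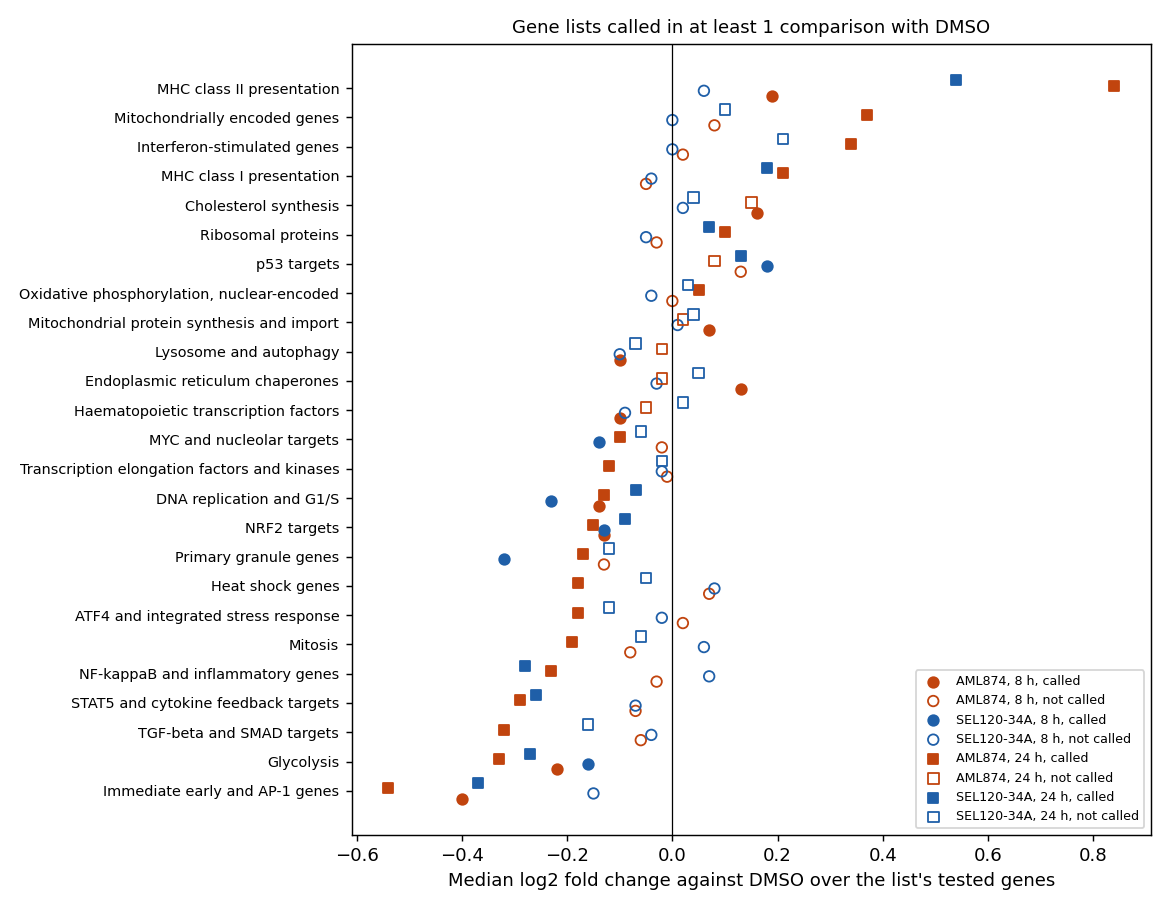
Median log2 fold change against DMSO of the 25 gene lists called by camera in at least 1 of the 4 comparisons, with filled symbols where the list was called. The MHC class II list lay at 0.84 with AML874 and 0.54 with SEL120-34A at 24 h, and the immediate early and AP-1 list at -0.54 and -0.37.

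The BCL2 family and the Mediator kinase genes were fixed for naming because of the title. BCL2, the target of venetoclax, rose by 0.12 ± 0.03 with AML874 at 8 h and by 0.23 ± 0.03 at 24 h, and with SEL120-34A by 0.24 ± 0.03 at 24 h. At 8 h with SEL120-34A, BCL2 was at 0.02 ± 0.03 and did not pass (95% interval -0.04 to 0.08), though it passed at 0.09 with library totals alone (adjusted p = 0.0115). MCL1, another anti-apoptotic member, had -0.17 ± 0.02 and -0.28 ± 0.02 with AML874 at 8 h and 24 h, and -0.12 ± 0.02 and -0.17 ± 0.02 with SEL120-34A. BCL2L1 had -0.32 ± 0.04 with AML874 and -0.18 ± 0.04 with SEL120-34A at 24 h. The pro-apoptotic gene PMAIP1 rose by 0.35 ± 0.07 with AML874 at 8 h (adjusted p = 0.000452). At 24 h PMAIP1 was at 0.20 ± 0.06 (adjusted p = 0.019), and it did not pass without replicate 2 or 3 of DMSO (adjusted p = 0.0901 and 0.0749), without replicate 1 or 2 of AML874 (0.0855 and 0.0521) or with a model of only the groups compared (0.0548). With SEL120-34A at 8 h PMAIP1 was at 0.16 and did not pass (adjusted p = 0.0556), though it passed in 8 alternatives with adjusted p from 0.000183 to 0.0458. BAX had -0.15 ± 0.03 with AML874 at 24 h, and BCL2L11, also pro-apoptotic, rose by 0.15 ± 0.03 with SEL120-34A at 24 h. Neither list of the BCL2 family was called against DMSO in any of the 4 comparisons.

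Smaller changes of this family at 8 h depended on single libraries or on the scaling. With AML874, BCL2L1 was at -0.12 ± 0.04 and did not pass without DMSO replicate 2 (adjusted p = 0.0796), without AML874 replicate 2 (0.0509) or with library totals alone (0.169). With SEL120-34A, BCL2L1 was at 0.11 ± 0.04 and BAK1 at 0.13 ± 0.04. Without DMSO replicate 1 or 3 or SEL120-34A replicate 3, BCL2L1 had adjusted p = 0.104, 0.241 and 0.297, and without DMSO replicate 3 or SEL120-34A replicate 3, BAK1 had 0.148 and 0.106. BAX was at -0.08 with each compound at 8 h and BCL2L11 at -0.13 with SEL120-34A, and with library totals alone these did not pass. CDK8, CDK19, CCNC and MED12, of the Mediator kinase module, did not pass in any of the 4 comparisons with DMSO as designed, with 95% intervals of -0.06 to 0.08 for CDK8 and -0.12 to 0.10 for CDK19 with AML874 at 8 h. With library totals alone, CDK8 and MED12 each passed at 0.10 with SEL120-34A at 8 h (adjusted p = 0.0142 for each). With the HIF target mean as a covariate, CDK19 passed at 0.14 with AML874 and 0.11 with SEL120-34A at 24 h (adjusted p = 0.0001 and 0.00131). CCNC, at -0.06 with SEL120-34A at 8 h, passed in 5 alternatives with adjusted p from 0.0336 to 0.0488. With AML874 at 8 h CCNC was at -0.06 (adjusted p = 0.0958) and passed without AML874 replicate 1 (0.0144) and without the 4 libraries highest on the main axis of variation within groups (0.0353). MED13, of the same module, had -0.27 ± 0.03 with SEL120-34A at 8 h. With AML874 at 8 h, MED13 was at -0.08 ± 0.03 (adjusted p = 0.04), and without DMSO replicate 3 or AML874 replicate 3 it did not pass (adjusted p = 0.101 and 0.119). The call also ended with library totals alone (-0.03, adjusted p = 0.47), the HIF covariate (-0.03, 0.398), the replicate block (0.0524), the filter of 1 CPM (0.057) and unstranded counts (0.0539). MYC had -0.23 ± 0.03 with AML874 at each time, and -0.15 and -0.12 with SEL120-34A.

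The direct comparison at 8 h asked where the compounds differed. BCLAF1 was higher with AML874 than with SEL120-34A by 0.76 ± 0.03 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.45e-21), and C5, a complement component, by 0.90 ± 0.06. MSMO1, of cholesterol synthesis, was higher by 0.75 ± 0.09, and PIGZ and ANGEL1 by 0.84 ± 0.08 and 0.74 ± 0.04. SCART1 had -1.41 ± 0.10, C3AR1 -1.23 ± 0.27, ZDHHC11 -1.53 ± 0.07, ABTB1 -1.12 ± 0.06 and TMEM71 -1.02 ± 0.07. Endoplasmic reticulum chaperones were higher with AML874 in 12 of 16, with CALR at 0.41 ± 0.02, and cholesterol synthesis genes in 13 of 24, with SQLE at 0.54 ± 0.05, while mitosis genes were lower in 16 of 26, with KIF20A at -0.36 ± 0.03. With an estimated correlation their adjusted p = 0.381, 0.663 and 0.568, and 0 of the 11 called lists held with it. Adjusted over the list alone, 12 chaperones and 14 cholesterol genes were higher and 18 mitosis genes lower. Between the compounds 6536 genes differed at 8 h, 3346 higher and 3190 lower with AML874, and the share of higher genes went from 51.2% to 43.4% with library totals alone.

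At 24 h, CLEC5A was lower with AML874 than with SEL120-34A by a log2 difference of -2.13 ± 0.13, and MPO by -1.34 ± 0.07. The serpin genes SERPINB2 and SERPINB10 had log2 differences of -1.68 ± 0.14 and -1.45 ± 0.10. Their annotated positions overlap on the same strand, and whether their changes are separate was not tested. ID2, an inhibitor of helix-loop-helix factors, was higher by 0.94 ± 0.05, RSAD2 by 0.69 ± 0.08 and HLA-DOA by 0.63 ± 0.10. The chemokine receptor gene CCR1 was higher by 0.72 ± 0.14 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00275), a call that ended with a model of only the groups compared (adjusted p = 0.0824). MHC class II genes were higher with AML874 in 7 of 10 (9 adjusted over the list alone), with HLA-DPA1 at 0.29 ± 0.03. Transcription elongation factors and kinases were lower in 9 of 21 (9 adjusted over the list alone), with HEXIM1 at -0.79 ± 0.04, CDK12 at -0.20 ± 0.03 and BRD3 at -0.20 ± 0.03. With an estimated correlation these lists had adjusted p = 0.0114 and 0.0082, and the other 14 of the 16 called lists did not hold.

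Among those 14, mitochondrially encoded genes were higher with AML874 in 12 of 13, with MT-ND1 at 0.37 ± 0.03, and mitosis genes were lower in 14 of 26, with MKI67 at -0.32 ± 0.03. Their adjusted p = 0.134 and 0.25 with an estimated correlation. Pro-apoptotic BCL2 family genes were lower in 5 of 8, with BBC3 at -0.43 ± 0.09 and BMF at -0.34 ± 0.08 (adjusted p = 0.309 with an estimated correlation), and adjusted over the list alone 6 were lower and 2 higher. The ATF4 list had a median of -0.12 and a mean of 0.04, and its test gave a fall. Of all genes, 4109 differed at 24 h, 1674 higher and 2435 lower with AML874. The share of higher genes, 40.7%, depended on the settings and was 49.2% with the filter of 1 CPM, 47.2% with only the groups compared and 45.0% with library totals alone.

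The responses to the compounds shared many genes. At 8 h, 2791 genes rose with both compounds, where independent lists of these sizes would share 925, and 2798 fell with both, against 941. At 24 h, 3076 rose with both, against 923, and 3206 fell with both, against 922. Of genes called with both, 94.5% at 8 h and 98.8% at 24 h changed the same way. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.77 at 8 h and 0.78 at 24 h. These comparisons share their DMSO libraries. In simulations without any effect, the treated and the shared DMSO libraries of a time were all drawn from the DMSO means. They gave a mean r of 0.51 and 0.49. Genes were drawn independently, so these simulations leave out variation that genes share within groups. The covariance was 0.249 observed and 0.044 simulated at 8 h, and 0.194 and 0.033 at 24 h. The 3 DMSO libraries of a time were too few to split into parts of more than 1 library, so a part of the excess from shared controls was not measured. Pairs of comparisons that share no library gave r = 0.52 for AML874 at both times, 0.48 for SEL120-34A at both times, and 0.47 and 0.41 between compounds across times.

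The last comparisons asked whether effects differed between 24 h and 8 h. The CD34 effect of AML874 was higher at 24 h by 2.24 ± 0.17, and that of SEL120-34A by 1.91 ± 0.17. The MPO effect of AML874 was lower by a log2 difference of -1.89 ± 0.09, and RBM14, which was lowered by SEL120-34A at 8 h, had an effect higher by 1.55 ± 0.05 at 24 h. MHC class II effects were higher at 24 h in 9 of 10 genes with each compound, with medians of 0.57 and 0.43. This list held with an estimated correlation with both compounds (adjusted p = 0.00582 and 0.0426), as did MHC class I presentation (adjusted p = 0.0408) and ATF4 targets (0.0274) with AML874. The effect differed between times in 4944 genes with AML874 and in 5706 with SEL120-34A (edgeR quasi-likelihood, Benjamini-Hochberg adjusted). Each time difference also holds the DMSO time difference, in which 8898 genes changed, 4151 higher and 4747 lower at 24 h.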

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

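These results were listed because a test of the difference itself found that the effect of a compound at 24 h differed from its effect at 8 h. The log2 difference of effects of AML874 was 2.24 for CD34, 1.90 for GBP4, 1.66 for GPR174, 1.52 for HLA-DOA and 1.42 for PCLO, a presynaptic scaffold gene. It was -1.89 for MPO, -1.84 for CCL2, -1.17 for TSPOAP1, -1.12 for ZFP36L1 and -1.06 for CLEC5A. For SEL120-34A it was 1.91 for CD34, 1.71 for SERPINB2, 1.55 for RBM14, 1.46 for GPR174 and 1.44 for SERPINB10. It was -2.58 for CCL2, -1.83 for C3AR1, -1.78 for ZFP36L1, -1.38 for SCART1 and -1.24 for CD300LF, an inhibitory myeloid receptor gene. CCL2 went from 9.01 to 18.0 CPM with SEL120-34A at 8 h and from 14.2 to 4.75 CPM at 24 h. All 20 passed the edgeR quasi-likelihood test.

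With AML874 the list medians of the difference were 0.57 for MHC class II, 0.32 for interferon-stimulated genes, 0.29 for mitochondrially encoded genes, 0.21 for MHC class I, 0.12 for ribosomal proteins, 0.11 for haematopoietic transcription factors and 0.10 for nuclear-encoded oxidative phosphorylation. They were -0.26 for ATF4 targets, -0.18 for STAT5 targets, -0.18 for cholesterol synthesis, -0.14 for heat shock genes, -0.12 for mitosis, -0.12 for glycolysis and -0.07 for endoplasmic reticulum chaperones. Beside the MHC and ATF4 lists, adjusted p with an estimated correlation ran from 0.365 to 0.713. With SEL120-34A the medians were 0.43 for MHC class II, 0.18 for DNA replication, 0.12 for MHC class I, 0.12 for ribosomal proteins, 0.10 for haematopoietic transcription factors and 0.08 for oxidative phosphorylation, and -0.26 for NF-kappaB genes, -0.17 for STAT5 targets and -0.17 for mitosis. Beside MHC class II, adjusted p with an estimated correlation ran from 0.441 to 0.7. With library totals alone the medians of MHC class I, ribosomal proteins, haematopoietic transcription factors and oxidative phosphorylation were 0.05, 0.05, 0.03 and 0.00 with SEL120-34A, and 0.16, 0.07, 0.06 and 0.05 with AML874. The haematopoietic transcription factors had a mean of -0.03, opposite in sign to their median and test.

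The difference was called in 4944 genes with AML874 and 5706 with SEL120-34A. Among 100 splits of the libraries, 6 called as many genes as the real groups of AML874, counting the real one, with up to 5743 genes. The 5 others kept the real groups at 1 of the times, and the 78 that kept neither called at most 0 genes. For SEL120-34A 1 of 100 did, the real one, and the highest other split, which also kept the real groups at 1 time, called 5616 genes. Splits of this kind hold an effect of the compound at 1 time and the others mix treated and control libraries, so no verdict on chance was drawn from these counts for either compound. For each of the 7 other comparisons 1 of 10 splits called as many genes, the real one, and the highest other count was 0, but 10 splits are too few to reach a share under 0.05. With library totals alone the share of higher differences was 30.7% in place of 47.1% with AML874 and 29.1% in place of 52.2% with SEL120-34A.

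For the tests below, those of antisense changes and depth were chosen before their results were seen, and those of antisense gains, the floor, the replicate axis, the HIF targets, B cells and scaling only after. The first pattern was that 2-fold rises outnumbered 2-fold falls. After every library was thinned to the smallest, rises still outnumbered falls by at least 3.43 to 1, which excludes depth. The median antisense change was at most 0.146 of the sense change in the 250 of 745, 355 of 1084, 382 of 892 and 227 of 568 genes with enough antisense counts, and over every gene that rose the antisense CPM gained a median of 0 and in sum -0.00252 to 0.0777 of the sense gain, which excludes unstranded background such as DNA. At 5 CPM or more, 17 genes rose and 14 fell with AML874 at 8 h (ratio 1.21, 95% interval 0.563 to 2.66), 27 and 10 with SEL120-34A at 8 h, 62 and 26 with AML874 at 24 h and 33 and 15 with SEL120-34A at 24 h, so a floor that hides falls of weakly expressed genes may account for a part. No biological explanation of it was tested.

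The second pattern was the fall of the glycolysis list. The main axis of variation within groups, with 37.2% of that variance, had 12 of 22 HIF targets among its 100 strongest genes. The HIF list was written after this axis was seen, so that count is no independent evidence of what the axis is. A shift of the treated cultures along this axis would have raised nucleolar genes (slope -0.321 ± 0.051), but these lay below the prediction in 4 of 4 comparisons, with differences of -4.5, -9.4, -8.3 and -6.8 standard errors. As the nucleolar list was itself called lower in 2 of these comparisons, this test leaves such a shift open. With the HIF target mean as a covariate the glycolysis median kept at least 0.455 of its size, going from -0.22 to -0.10 and from -0.16 to -0.11 at 8 h, where the call ended with the smaller change (adjusted p = 0.18 and 0.0728), and from -0.33 to -0.24 and from -0.27 to -0.21 at 24 h, where it stayed (adjusted p = 6.9e-05 and 5.33e-06). HIF targets fell in 6, 5, 7 and 5 of 22 genes, in the order AML874 and SEL120-34A at 8 h and then at 24 h. Camera with the preset correlation gave the list unadjusted p = 0.00234, 0.0887, 0.0192 and 0.0247 in that order. With an estimated correlation the list did not hold (unadjusted p = 0.468, 0.682, 0.575 and 0.59), so a lower HIF response stays open.

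The third pattern was the rise of MHC class II genes at 24 h. B lymphocytes carry these genes, but the sum of 8 B cell transcripts went from 1.37 ± 0.206 CPM to 0.947 ± 0.0625 with AML874 and 0.921 ± 0.144 with SEL120-34A, while MHC class II counts went from 1551 to 2238 and 2043 CPM. The change of the B cell sum was at most -0.0609% of the MHC class II change, which excludes B lymphocytes. With library totals alone the medians were 0.84 and 0.53. As the TMM factors at 24 h were 0.986 to 1.016, this setting could hardly have given other values. The list median lay at least 0.535 above the median of all tested genes. A scaling factor moves all genes of a library alike and cannot make such a gap, but the gap restates the rise and is no separate test of it. The effect of each compound on this list grew with time and CIITA rose with it, while reads shared between HLA genes and variants of this line against the reference were not tested.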

How the results depend on the processing

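Every total of changed genes stayed within 1.5 times its value in all settings, but the genes were not all the same. Of the 9425 genes of SEL120-34A at 8 h, 7824 were called again with library totals alone and 9150 with limma-voom. Of the 5706 genes whose SEL120-34A effect differed between times, 4538 were called again with library totals alone. The 2-fold counts did not: with a filter of 1 CPM in 3 libraries, which leaves 13527 genes and removes weakly expressed ones, 168 rose and 32 fell with AML874 at 8 h, 240 and 37 with SEL120-34A at 8 h, 242 and 70 with AML874 at 24 h and 131 and 37 with SEL120-34A at 24 h. Leaving out 1 library gave 7477 to 7778 genes for AML874 and 8518 to 9020 for SEL120-34A at 8 h, 8829 to 9076 and 6890 to 7250 at 24 h, and 3067 to 3985 between the compounds at 24 h. Of 349 gene results, limma-voom and median-of-ratios size factors kept all 349 in direction and side of the threshold. Most of these results were picked by the main test for a small p or a large change. That they held therefore says little about genes near the threshold. Leaving out each library in turn gave each gene several values, of which 2196 were kept, 13 weaker and 5 stronger. Library totals alone kept 340. CDK19 with AML874 at 8 h reversed, from -0.01 without passing to 0.10 (adjusted p = 0.0113), with the HIF target mean as a covariate, and the cause was not tested.

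Among genes above median expression the correlation of fold changes moved to 0.88 between compounds at 24 h, 0.66 for AML874 at both times, 0.55 for SEL120-34A at both times, 0.56 for AML874 at 8 h with SEL120-34A at 24 h and 0.52 for the reverse. Leaving out 1 library lowered the last 4 to 0.46 to 0.48, 0.42 to 0.44, 0.40 to 0.43 and 0.36 to 0.39, with 21351 to 21439 genes tested, so more weakly expressed genes entered.

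In the order of the 9 comparisons, camera called 10, 6, 19, 10, 11, 16, 11, 14 and 9 lists. An estimated correlation left 0, 0, 1, 1, 0, 2, 0, 3 and 1. The estimates for each list are not given here, so why the other calls ended is left open. The rotation test fry called 25, 15, 32, 26, 22, 20, 27, 21 and 17. It asks whether the members of a list shifted in 1 direction, without comparing them with other genes. With the HIF target mean as a covariate 7 lists differed between compounds at 8 h, and the cause was not tested. Libraries with the same replicate number were not alike (45 pairs, correlations from -0.58 to 0.54, median 0.00), and a block for it changed no list call.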

Other observations

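In DMSO alone, from 8 h to 24 h, cholesterol synthesis genes rose in 21 of 24, with SREBF2 at 0.52 and a median of 0.48, and cell cycle inhibitors in 7 of 10, with CDKN1B at 0.26. MYC and nucleolar targets fell in 24 of 26, with NOLC1 at -0.32, and mitochondrial protein synthesis and import in 23 of 26. NRF2 targets fell in 10 of 14, with NQO1 at -0.76. Adjusted p with an estimated correlation ran from 0.335 to 0.536 over the 11 lists called. BCL2 rose by 0.35. The share of higher genes was 46.7%, and 57.1% with library totals alone. With the HIF target mean as a covariate 6521 genes changed in place of 8898. The median of cell cycle inhibitors then went from 0.25 to 0.15 and their call ended (adjusted p = 0.092), while that of nucleolar targets went from -0.27 to -0.18 and stayed called.

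The monocyte and macrophage list was not called with either compound at 24 h (adjusted p = 0.16 and 0.0679), with 6 rises and 9 falls of 26 with AML874 and 4 rises and 11 falls with SEL120-34A. LYZ, the lysozyme gene, had -0.58 and -0.34, and CSF1R, the receptor of a macrophage growth factor, -0.98 and -0.70. The stem and progenitor list was not called either (adjusted p = 0.621 and 0.472), though KIT rose by 1.97 ± 0.25 and 1.66 ± 0.25 and FLT3 by 0.54 ± 0.05 and 0.46 ± 0.05. The Mediator kinase module list was not called against DMSO (adjusted p = 0.737, 0.744, 0.912 and 0.762). Lists of other cell types had 4 erythroid and megakaryocyte genes, 6 lymphocyte genes and 3 fibroblast and epithelial genes tested, and none was called in the 9 comparisons, though lists this small have little power and single members changed.

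With AML874 at 24 h the lymphocyte markers had a median of 1.40, with 3 rises and 2 falls of 6. PRF1, the perforin gene, rose by 2.57 ± 0.41, to 0.271 CPM, IGKC by 2.78 ± 0.54, to 0.176 CPM, and PAX5 by 2.24 ± 0.60, to 0.145 CPM, while CD79A had -1.66 ± 0.19 and NKG7 -0.47 ± 0.11. Their median was 0.86 with AML874 at 8 h, 0.16 with SEL120-34A at 8 h and 0.24 at 24 h. The erythroid and megakaryocyte markers had medians of 0.99 with AML874 and 0.73 with SEL120-34A at 24 h, with VWF at 2.79 ± 0.71, to 0.11 CPM, and ITGA2B at 0.53 ± 0.14 with AML874, and 3 and 1 rises of 4. The fibroblast and epithelial markers had 0.60 and 0.32, with FBN1 at 0.42 ± 0.06 and 0.32 ± 0.06. Adjusted p of the 3 lists was 0.602, 0.167 and 0.212 with AML874 at 24 h.

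Within groups, DDIT4, PFKFB4, SLC2A3, ENO2, BNIP3, CXCL8 and EGR1 were at the high end of the main axis, and METTL1, POLR1G and NOL6 at the low end. Replicate 3 of DMSO at 8 h (4.6), replicate 2 of SEL120-34A at 8 h (4.5) and at 24 h (5.0) and replicate 1 of AML874 at 24 h (2.9) had the highest scores.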
